A study of Homo sapiens with 8 samples.

How the data were processed

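Dimethylation of lysine 4 of histone H3 (H3K4me2), a chromatin mark found at promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in OCI-Ly1 and OCI-Ly7, 2 established human diffuse large B cell lymphoma lines. Per the labels' protocols, cells were fixed for 10 min in formaldehyde at 1%. Chromatin fragments of 200 to 400 bp were precipitated with an antibody against H3K4me2 and sequenced. The series lists 8 samples, which are 2 H3K4me2 libraries of each line, described as biological replicates, and an input sample for each. The 4 input samples were not analysed here.

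Each H3K4me2 library came with 1 list of peaks made by the authors. Per the submitters' processing notes, the genome build was hg18 and CASAVA was among the tools used; the peak caller and its settings are not given in the sources used here. Per the file headers, each peak has a start and an end, an average p-value, a score, the position and height of its maximum, and a size in bp. The deposited average p-value is a logarithm whose base the headers do not name, and its highest value in each list lay between -15.0 and -15.04, which shows a threshold near -15 in all 4 lists. It was given as minus infinity for 287, 1236, 167 and 207 peaks of OCI-Ly1 replicate 1, OCI-Ly1 replicate 2, OCI-Ly7 replicate 1 and OCI-Ly7 replicate 2. The deposited score is the peak caller's own number, and was used here only to rank the peaks within a list. The deposited peak height is a whole-number signal at the maximum of the peak, with no scaling by depth stated in the file headers. Peaks of one list never overlapped and lay at least 101 bp apart, and the narrowest peak was 99 bp wide. The number of reads per library is not given in the sources used here, so the depth is unknown. The length of a list and the peak heights, if these were not scaled, are indirect guides to it: the median height in shared regions was 71 in OCI-Ly1 replicate 1 and 114, 100 and 99 in OCI-Ly1 replicate 2, OCI-Ly7 replicate 1 and OCI-Ly7 replicate 2. Coordinates are printed as the authors' files give them, on hg18.

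A sample's line and replicate number were taken from its title. The cell line tag of the libraries titled OCI-Ly7 reads OCI-Ly1, against their titles and the title of the series, and the titles were followed.

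Peaks of the 4 lists were joined into merged regions where they overlapped by at least 1 bp. A region was called shared when all 4 libraries had a peak in it, and restricted to a line when both libraries of that line and neither library of the other had one. Absence means that no peak passed the authors' threshold, not that the mark was absent. The overlap of 2 lists was measured as the Jaccard index, the percentage of bases covered by either list that both cover, and as the percentage of peaks overlapped. Its background came from 100 random circular shifts of one list along each chromosome. Because 4 libraries can be split 2 against 2 in only 3 ways, no permutation test of the lines can give a two-sided p under 0.333. The counts for the other splits are given in place of a p-value, as a description. They are not a background, since a region restricted to a line cannot fall in another split. Exact permutation tests compared measures per library. Per chromosome (22 autosomes and X), the numbers of regions restricted to each line were compared with those on all other chromosomes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 23 chromosomes. Regions are not replicates and neighbouring regions are not independent, so these p-values describe these 4 libraries, and 10000 permutations of 5 Mb blocks between chromosomes were run beside them. Intervals are 95% Wilson intervals for shares and 95% order-statistic intervals for medians, and cover counting error only.

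The lists name no genes, and no annotation of hg18 was used here. The planned comparisons of promoters, gene lists and location relative to genes were therefore not made, and regions are named by position. By a rule fixed before the data were examined, the named regions are the 10 widest restricted to each line and the 5 widest shared by all 4 libraries. The alternatives tried were the better 50% of each list by score, the same number of best peaks in every list (44605), each library left out in turn, reciprocal 50% overlap, joining across gaps of up to 1 kb, summits within 500 bp in place of whole peaks, a peak in at least 1 library of a line, only peaks of at least the median width of 552 bp, and the libraries grouped by replicate number. After the data were seen, regions with strong peaks only, regions over 5 kb from the other line's peaks, counts from 1 library per line and the replicate number as a block for the peak counts were added. Regions on other chromosomes (174) entered the counts over the genome, also that of regions over 5 kb from the other line's peaks. They entered no comparison by chromosome, and not the distances given for the autosomes and X.

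The code was tested on simulated data, 4 lists built from 42000 regions placed on the real chromosomes with widths drawn from the real peaks. It recovered 100% of the shared regions and 100% of those restricted to either line, and called 1 chromosome, the 1 that had been made to differ. Each simulated region stood apart and had a peak in every library of its class. No list was shorter than its replicate, and regions were not clustered. The result therefore checks the counting only, not the performance on the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.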

Results

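H3K4me2, a histone mark of active and poised promoters and enhancers, was mapped in 2 biological replicates each of OCI-Ly1 and OCI-Ly7, established human diffuse large B cell lymphoma lines of the germinal centre type. The 4 peak lists held 44605 peaks in OCI-Ly1 replicate 1, 63654 in OCI-Ly1 replicate 2, 64423 in OCI-Ly7 replicate 1 and 65667 in OCI-Ly7 replicate 2. The marked part of the genome was 36.9 Mb and 51.4 Mb in the OCI-Ly1 libraries and 50.9 Mb and 52.8 Mb in the OCI-Ly7 libraries. A typical peak was about as wide in every library, with medians of 565, 538, 556 and 553 bp in the same order, and the widest peak of each list spanned between 15852 and 18471 bp. OCI-Ly1 had 54129.5 ± 13469.7 peaks per library (SD, n = 2) and OCI-Ly7 65045 ± 880 (SD, n = 2), a difference smaller than the spread between the OCI-Ly1 replicates (two-sided exact permutation test, p = 0.333, the smallest that 2 against 2 libraries allow). The short list of OCI-Ly1 replicate 1 sets how many regions can be called in OCI-Ly1 below.

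The first comparison asked whether the mark covers the same places in replicates of a line and in the 2 lines. By the Jaccard index, libraries of the same line resembled each other more than libraries of different lines did. The OCI-Ly7 replicates shared 80.9% of their covered bases and the OCI-Ly1 replicates 65.5%. The 4 pairs of libraries from different lines shared between 38.3% and 48.3%, with a mean of 43.4% ± 4.38 (SD, n = 4 pairs), so both pairs within a line lay above every pair between lines. After random shifts along the chromosomes, the mean overlap was between 0.790% and 0.953%. The overlap between the 2 lines was far above this background. The shifts place peaks without regard to where the mark can occur, so the background is low for any 2 maps of the mark. It does not measure how alike these lines are. Of the peaks of OCI-Ly1 replicate 1, 97.4% overlapped a peak of replicate 2, while 64.5% of the peaks of replicate 2 overlapped one of replicate 1. In OCI-Ly7 the figures were 90.6% and 87.1%. By this measure OCI-Ly1 replicate 2 was no closer to its own line. Of its peaks, 64.8% and 64.3% overlapped a peak of OCI-Ly7 replicates 1 and 2, against 64.5% for its own replicate, whose list is the shortest. In the remaining libraries the percentage was lower with the other line than with the own replicate, at most 76.1%. No peak had the same start and end in both libraries of a line.

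**Figure D1:**
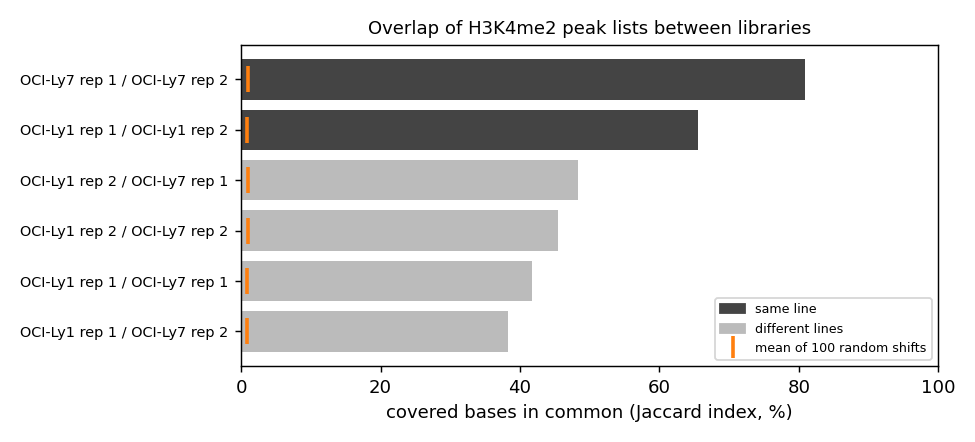
Overlap of each pair of peak lists. Bars give the covered bases in common (Jaccard index, %) for pairs from the same line (dark) and from different lines (light), and ticks the mean of 100 random shifts; the pairs within a line reach 65.5% and 80.9%, and the pairs between lines at most 48.3%.

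The second comparison asked which regions carry the mark in 1 line only. The 4 lists joined into 82690 merged regions. Of these, 27857 regions (33.7%, 95% Wilson interval 33.4 to 34.0) were marked in all 4 libraries, 7412 (8.96%, 8.77 to 9.16) were restricted to OCI-Ly1 and 15290 (18.5%, 18.2 to 18.8) were restricted to OCI-Ly7. The split by line separated 22702 regions in total. Grouping the libraries by replicate number separated 771, and the remaining way to pair them separated 593. In these 2 splits the pair with OCI-Ly1 replicate 1 held only 37 and 17 regions and the pair with OCI-Ly1 replicate 2 held 734 and 576. The short list thus limits these counts. A further 23201 regions (28.1%) had a peak in a single library, and 12432 of these belonged to OCI-Ly1 replicate 2. Among the 7566 regions found in 3 libraries, the missing library was OCI-Ly1 replicate 1 in 6092.

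The number restricted to OCI-Ly7 was 2.06 times the number restricted to OCI-Ly1, and this ratio was not stable. With the same number of best peaks in every list it was 1.07, from 8981 against 8417 regions. Without OCI-Ly1 replicate 1 it turned to 0.777, from 15409 against 19844 regions, but OCI-Ly1 regions then need a peak in 1 library and OCI-Ly7 regions in 2. With 1 library per line, added after seeing the data, the ratio was 2.88 and 3.12 with OCI-Ly1 replicate 1, and 0.891 and 1.03 with OCI-Ly1 replicate 2. Which line has more regions of its own cannot be read from these lists, whereas the split by line separated far more regions than either other split. With the better 50% of each list by score, 3664 regions were restricted to OCI-Ly1 and 6781 to OCI-Ly7.

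**Figure D2:**
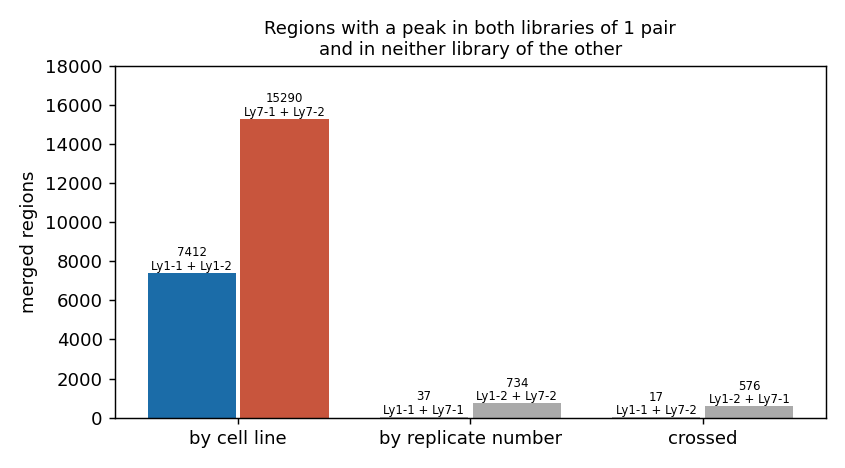
Merged regions (count) with a peak in both libraries of 1 pair and in neither of the other, for the 3 ways to split the 4 libraries. The split by line gives 7412 regions for OCI-Ly1 and 15290 for OCI-Ly7, and no pair made of both lines exceeds 734.

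Shared regions were wider and their peaks taller than those restricted to a line. The median width was 1327 bp (95% interval 1315 to 1340) for shared regions, 659 bp (646 to 672) for regions restricted to OCI-Ly1 and 520 bp (511 to 527) for regions restricted to OCI-Ly7. Merging 4 lists widens a region more than merging 2, so the peaks of each library were also compared within that library. This does not remove selection by the threshold: a region must pass it in 4 lists to be shared, which favours strong, wide peaks by definition, so the size of the difference is not a measure of the lines. In OCI-Ly1 replicate 1 the median peak width was 692 bp in shared and 328 bp in restricted regions. In OCI-Ly1 replicate 2 it was 888 and 596 bp, in OCI-Ly7 replicate 1 it was 784 and 363 bp, and in OCI-Ly7 replicate 2 it was 784 and 448 bp. Median peak heights in shared and restricted regions were 71 and 36, 114 and 65, 100 and 46, and 99 and 50 in the same order of libraries. Restricted regions were not all weak: between 23.3% and 30.1% of their peaks lay in the taller 50% of the list in OCI-Ly1 replicate 1 and both OCI-Ly7 libraries. In OCI-Ly1 replicate 2 the share was 49.8%, which is raised by selection, since these regions also need a peak in the short list of replicate 1. Regions of at least 5 kb were mostly shared, with 728 in all 4 libraries (2.61% of shared regions), 20 restricted to OCI-Ly1 (0.270%) and 23 restricted to OCI-Ly7 (0.150%). The median widths of restricted regions depended on the lists. Without OCI-Ly1 replicate 1 that of OCI-Ly1 was 301 bp, and with the better 50% of each list those of OCI-Ly1 and OCI-Ly7 were 1051 and 1070 bp, against 1593 bp for shared regions.

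Regions restricted to a line often lay some distance from any peak of the other line. The median distance to the nearest such peak was 10.3 kb for the 7402 regions restricted to OCI-Ly1 on the autosomes and X, and 6.06 kb for the 15249 restricted to OCI-Ly7. At most 1 kb separated 16.5% and 23.4% of them from a peak of the other line. Whether these lie at the edge of a domain that both lines carry was not tested. More than 5 kb separated 63.5% and 53.0%, and more than 100 kb 10.78% and 11.05%. After seeing the data, regions were also counted whose peaks were in the better 50% of both lists of a line and where the other line had no peak of any strength; there were 1702 such regions in OCI-Ly1 and 3074 in OCI-Ly7.

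The 10 widest regions restricted to OCI-Ly1 spanned 7528 to 14426 bp. The widest lay on chromosome 8 from 60179876 to 60194302, with a maximum peak height of 143 in replicate 1 and 222 in replicate 2. Another of 9276 bp lay on the same chromosome from 60096706 to 60105982, with heights of 83 and 140. OCI-Ly7 peaks were close to both, 0.366 kb and 5.74 kb away. In the window from 60119876 to 60254302 on chromosome 8, the OCI-Ly1 libraries had 29 and 26 peaks and the OCI-Ly7 libraries 3 and 2. The second widest lay on chromosome 13 from 98746818 to 98758853 (12035 bp), with heights of 129 and 202, and the third on chromosome 4 from 100784097 to 100795116 (11019 bp), with heights of 83 and 135. A region of 9572 bp on chromosome X, from 33258996 to 33268568, was 147 kb from the nearest OCI-Ly7 peak. A region of 9126 bp on chromosome 10, from 84252651 to 84261777, was 778 kb from one, the largest distance of the 10. The others were on chromosomes 10 (2 regions), 2 and 3.

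The 10 widest regions restricted to OCI-Ly7 spanned 5902 to 8482 bp. The widest lay on chromosome 3 from 154942848 to 154951330, with maximum peak heights of 182 and 194 in the 2 replicates, and the nearest OCI-Ly1 peak was 382 kb away. In the window from 154882848 to 155011330 around it, the OCI-Ly7 libraries had 9 and 8 peaks and the OCI-Ly1 libraries 0 and 0. The second lay on chromosome 11 from 33451109 to 33459382 (8273 bp), with heights of 188 and 160, and was 83.0 kb from the nearest OCI-Ly1 peak. The third lay on chromosome 3 from 53175005 to 53182560 (7555 bp), with heights of 113 and 120. On chromosome 2 a pair of regions, from 180426767 to 180433828 and from 180451937 to 180458337, spanned 7061 and 6400 bp and were 0.696 kb and 17.1 kb from the nearest OCI-Ly1 peak. The others were on chromosomes 2, 5, 6, 8 and X.

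**Figure D3:**
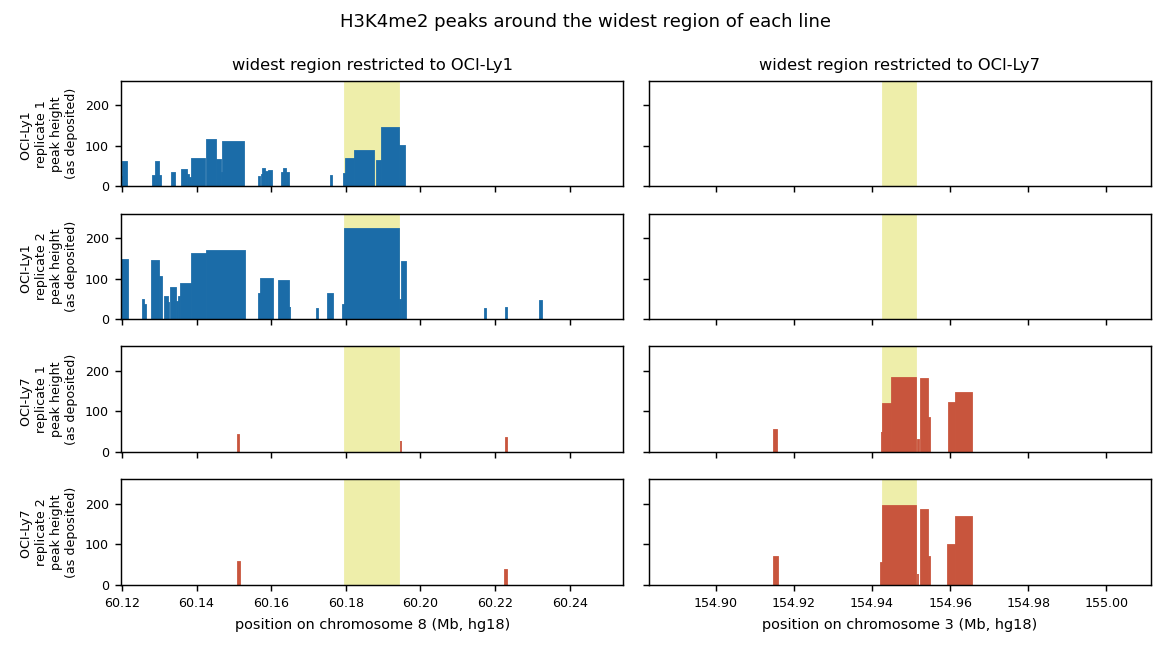
Peaks around the widest region restricted to each line (shaded). The horizontal axis is the position in Mb on hg18, each row is a library, and each block spans 1 peak and is drawn to its maximum height (signal as deposited); the chromosome 8 window holds 29 and 26 OCI-Ly1 peaks against 3 and 2 in OCI-Ly7, and the chromosome 3 window 9 and 8 OCI-Ly7 peaks against none in OCI-Ly1.

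The widest regions marked in all 4 libraries were 17 to 18 kb long. The widest lay on chromosome 5 from 124095441 to 124113928 (18487 bp), with heights of 134 and 220 in OCI-Ly1 and 176 and 193 in OCI-Ly7. It was 1 unbroken peak in each OCI-Ly1 library, and 5 and 4 peaks in the OCI-Ly7 libraries. The next lay on chromosome 2 from 64716609 to 64734444 (17835 bp), on chromosome 11 from 64938842 to 64956568 (17726 bp), on chromosome 5 from 158449487 to 158466814 (17327 bp) and on chromosome 1 from 224906229 to 224923288 (17059 bp). In the last of these the heights were 73 and 110 in OCI-Ly1 and 173 and 168 in OCI-Ly7; whether heights were scaled by depth is not given in the sources used here, and this difference was not tested.

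The last comparison asked whether the regions restricted to each line were spread alike over the chromosomes. Over the autosomes and X, 32.7% of the line-restricted regions were restricted to OCI-Ly1. Chromosome 7 had the highest share of OCI-Ly1 regions, 43.9% (95% Wilson interval 41.1 to 46.7; 534 against 682 regions; odds ratio 1.66; Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 1.05e-15). Chromosome 21 had 41.5% (35.7 to 47.5; adjusted p = 0.00794, Fisher's exact test) and chromosome 13 had 40.9% (37.1 to 44.9; adjusted p = 0.000113, Fisher's exact test). Chromosome 12 had the lowest share, 23.8% (21.4 to 26.3; 277 against 888 regions; odds ratio 0.629; adjusted p = 1.30e-10, Fisher's exact test). Chromosomes 20, 3, 6 and 1 also had lower shares, of 26.6%, 28.5%, 29.0% and 29.1%, with adjusted p of 0.00174, 0.00174, 0.0128 and 0.00174 by Fisher's exact test. These 8 of 23 chromosomes passed the test. With the same number of best peaks in every list 16 passed, without OCI-Ly1 replicate 1 13 passed, and with the better 50% of each list 12.

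In each of the 4 pairs of 1 OCI-Ly1 and 1 OCI-Ly7 library, chromosome 7 lay above and chromosome 12 below the share over all chromosomes. For OCI-Ly1 replicate 1 against OCI-Ly7 replicate 1 these shares were 34.5% on chromosome 7, 18.3% on chromosome 12 and 25.7% over all chromosomes, and for OCI-Ly1 replicate 2 against OCI-Ly7 replicate 2 they were 61.7%, 40.7% and 49.2%. Restricted regions cluster, which makes Fisher's test too ready to call a chromosome. When 5 Mb blocks were permuted between chromosomes, only chromosome 7 kept an adjusted p under 0.05 (permutation test, adjusted p = 0.0138), and chromosome 12 had an adjusted p of 0.101. Blocks were treated as independent of their neighbours, so clusters wider than 5 Mb would make these p-values too small as well.

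**Figure D4:**
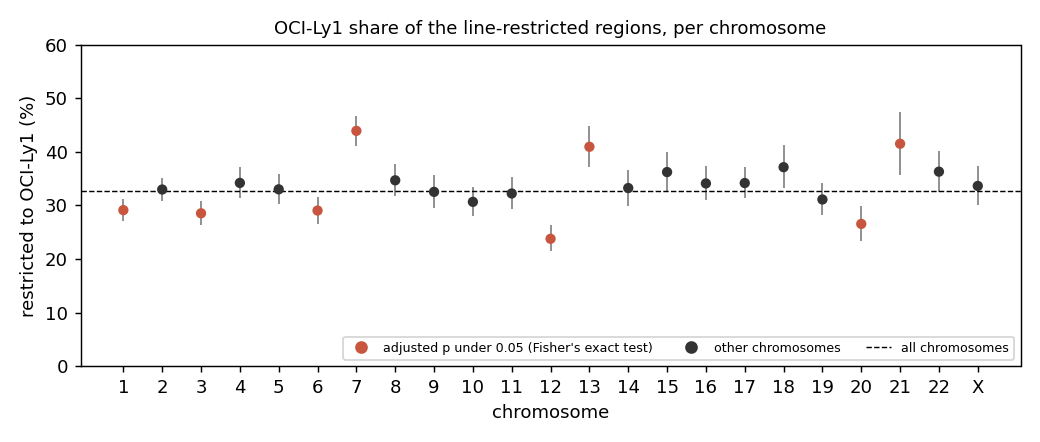
Share (%) of the line-restricted regions of each chromosome that were restricted to OCI-Ly1, with 95% Wilson intervals and the share over all chromosomes (dashed, 32.7%). Red points passed Fisher's exact test at an adjusted p under 0.05, of which only chromosome 7, highest at 43.9%, also passed with permuted 5 Mb blocks; chromosome 12 is lowest at 23.8%.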

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

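The alternatives of strong peaks, of a 5 kb distance to the other line, of 1 library per line, of permuted blocks and of a replicate block were chosen after seeing the data; all others were fixed before. The split by line separated 22702 regions and the split by replicate number 771. The samples share only a number. With the replicate number as a block, the mean difference in peaks, OCI-Ly7 minus OCI-Ly1, stayed 10915.5, from 19818 and 2013 in the 2 pairs (two-sided exact sign-flip permutation p = 0.5, the smallest for 2 pairs). For the counts of merged regions no blocked fit was made, since they come from no test. With the better 50% of each list, 3664 regions were restricted to OCI-Ly1 and 6781 to OCI-Ly7. With the same number of best peaks in every list, the OCI-Ly7 count fell to 8981 and the ratio of OCI-Ly7 to OCI-Ly1 to 1.07. With a peak in at least 1 library of a line enough, the counts were 20704 and 25199 and the ratio 1.22. With both peaks in the better 50% they were 1702 and 3074, and with no peak of the other line within 5 kb 4705 and 8117. Joining across 1 kb left 8832 for OCI-Ly7. Leaving out 1 library at a time gave 7879 to 19844 regions for OCI-Ly1, 15409 to 21899 for OCI-Ly7 and ratios from 0.777 to 2.64; the count of 19844 and the ratio under 1 came from leaving out OCI-Ly1 replicate 1. A line with a library left out needs a peak in 1 library and the other line in 2, which by construction raises its count. With 1 library per line the ratios were 2.88 and 3.12 for OCI-Ly1 replicate 1 against OCI-Ly7 replicates 1 and 2, and 0.891 and 1.03 for OCI-Ly1 replicate 2. Reciprocal 50% overlap lowered the mean share of peaks overlapped from 84.9% to 65.0% within lines and from 65.1% to 37.95% between lines; between lines it was 69.99% with the better 50% and 68.9% with equal list lengths. Median widths of shared, OCI-Ly1 and OCI-Ly7 regions were 1593, 1051 and 1070 bp with the better 50%, 1425, 752 and 815 bp with equal list lengths, and 2541, 878 and 709 bp when joined across 1 kb; leaving out a library gave 1181 to 1323, 301 to 656 and 368 to 562 bp. Shared regions were the widest class in each of these settings. The number of chromosomes past the threshold, 8, became 16 with equal list lengths and 1 with permuted blocks. It was 9 to 13 when a library was left out. By Fisher's exact test, chromosomes 7, 12 and 13 kept their direction and an adjusted p under 0.05. This held with stricter lists, lists of equal length and each library left out. With permuted blocks their adjusted p was 0.0138, 0.101 and 0.340 (permutation test). No other chromosome was followed by name through these settings. Peaks of at least the median width numbered 26974.5 per OCI-Ly1 library and 32641.5 per OCI-Ly7 library on average. In all, 41 values of these results moved and 2 reversed, while 59 stayed within 1.5 times for counts and ratios, within 1 SD for means, or within the 95% interval for widths. Part of the 59 stayed by construction and is no sign of stability. With so few libraries, leaving out 1 cannot move a mean of peak numbers or overlaps by over 1 SD. The replicate block cannot change the mean difference. The cause of a change was not tested, except that stricter lists hold fewer peaks by construction. The alternatives for promoters, gene lists and location were not run, since no hg18 annotation was used. With unknown read numbers, a region missing from a list cannot be told from one below the threshold.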

Other observations

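All tests of height ranks, by chromosome and by 5 Mb block, the permutation of blocks between chromosomes and the ratios from 1 library per line were chosen after the results they bear on were seen. Peaks called in both libraries of 1 line and neither of the other lay in long runs. Among regions that were shared or restricted to a line, the longest unbroken run restricted to OCI-Ly1 held 24 regions, on chromosome 8 from 2199536 to 3182122. Here the OCI-Ly1 libraries had 38 and 44 peaks and the OCI-Ly7 libraries 0 and 2. The next held 19 regions, on chromosome 7 from 145434316 to 147570869, with 21 and 62 OCI-Ly1 peaks and no OCI-Ly7 peak over 2137 kb. In OCI-Ly7 the longest run held 32 regions, on chromosome 1 from 17651836 to 19127233, with 43 and 45 peaks against 0 and 3 in OCI-Ly1. A run of 31 regions lay on chromosome 20 from 45878591 to 46955091, with 45 and 41 peaks against 0 and 2. A run of 29 regions on chromosome 3, from 23361351 to 23775543, had 35 and 39 peaks against 0 and 2 within 414 kb. When peaks were joined across 5 kb, the runs on chromosomes 7, 1 and 20 were still among the 5 longest of their line, with 19, 18 and 16 regions, and those on chromosomes 8 and 3 were not. The joined run on chromosome 7 was wider and its span held 5 and 7 OCI-Ly7 peaks.

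Blocks of 5 Mb also differed in how tall their shared peaks stood within a library. Shared regions on the autosomes and X were ranked by height within each library, so that each library ranks the same regions, and the rank in OCI-Ly1 minus that in OCI-Ly7 was taken. Of 436 blocks with at least 20 shared regions, 154 were higher in OCI-Ly1 and 127 higher in OCI-Ly7 in all 4 pairs of libraries, 281 in total. The 4 pairs share libraries, so some such blocks can arise with no line difference. The split by replicate number gave 113 and the remaining split 13. These counts are not a background: a line difference pulls their pairs between lines in opposite directions and so lowers both. Whether the larger count for the replicate number reflects a batch was not tested. The far end of chromosome 13, from 110 to 115 Mb, was 51.6 percentile points higher in OCI-Ly1, with 45.8 to 61.5 over the 4 pairs and 53 shared regions. It held 50 regions restricted to OCI-Ly1 and 5 restricted to OCI-Ly7. On chromosome 8 the block from 10 to 15 Mb had a difference of -40.4 points, with 4 regions restricted to OCI-Ly1 and 60 to OCI-Ly7, while the block from 140 to 145 Mb had 28.2 points, with 41 and 18. On chromosome 12 the blocks from 100 to 105 Mb and 105 to 110 Mb had differences of -28.1 and -30.2 points, with 8 and 8 regions restricted to OCI-Ly1 against 60 and 91. Not every block paired the 2 measures: on chromosome 7 the block from 140 to 145 Mb was 26.1 points higher in OCI-Ly1 and held 6 regions restricted to OCI-Ly1 and 29 restricted to OCI-Ly7. Neighbouring blocks were alike (Pearson's r = 0.50 over 327 pairs, 0.41 without chromosome 7; permutation test p = 0.0001, the smallest that 10000 permutations can give).

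The first pattern is the larger number of regions restricted to OCI-Ly7, 2.06 times that of OCI-Ly1. A candidate explanation is the short list of OCI-Ly1 replicate 1, since a region counts for OCI-Ly1 only if that library also has it. The ratio came to 1.07 with lists of equal length, as this explanation predicts. Equal lengths draw the counts together even if the lines truly differ, so this cannot tell a short list from a true difference. With 1 library per line, both lines follow the same rule. The ratio was then 0.891 and 1.03 with OCI-Ly1 replicate 2, and 2.88 and 3.12 with the short list. These ratios go with the list lengths: 44605 and 63654 peaks in OCI-Ly1 replicates 1 and 2, 64423 and 65667 in OCI-Ly7. They are no separate evidence for the explanation. A true difference in the extent of the mark between the lines stays open, untested, because the read numbers behind the lists are unknown.

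The second pattern is the high share of OCI-Ly1 among restricted regions on chromosome 7, and its counterparts in other segments. Permuting 5 Mb blocks gave p = 0.000600 for chromosome 7 (permutation test) before adjustment and 0.0138 after. This argues against clusters of regions within 5 Mb as the whole cause. It does not cover wider clusters, since blocks were treated as independent while neighbouring blocks were alike in height rank. A difference in DNA dose over the chromosome may be a source: shared regions on chromosome 7 ranked at least 13.3 percentile points higher in OCI-Ly1 in each pair of libraries. Over 408 blocks of the other chromosomes the rank difference and the OCI-Ly1 share of restricted regions correlated with r = 0.41 (Spearman's rho = 0.35, circular shift permutation p = 0.00245 for each, the smallest that the shifts can give; r = 0.37 without the 2 farthest blocks), while over 23 chromosomes r was 0.54 (permutation p = 0.0116, adjusted 0.0154 over 4 tests of 2 relations) and rho 0.39 (p = 0.0635), with r = 0.41 (p = 0.0625) without chromosomes 7 and 11, no longer under 0.05. The OCI-Ly1 share was 55.7% in the 18 blocks at least 20 points higher in OCI-Ly1 and 15.3% in the 12 at least 20 points higher in OCI-Ly7. In the 202 blocks with a difference under 5 points it was 31.7%, against 32.4% in all 436. These 202 blocks held 3085 of 6628 regions restricted to OCI-Ly1 and 6649 of 13848 restricted to OCI-Ly7. They also held 13089 of 26316 shared regions, so many restricted regions lay where ranks hardly differed, about in proportion to shared ones. Chromosome 11 ranked 9.24 points higher in OCI-Ly1 with an OCI-Ly1 share of 32.2%. A chromatin difference over megabases would give the same ranks, and the input libraries were not analysed here.

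The third pattern is the long runs of restricted regions. A chance order of the classes is argued against: in 1000 shuffles within chromosomes the longest run was at most 9 regions for OCI-Ly1 and 18 for OCI-Ly7, against 24 and 32 observed (permutation p = 0.000999 for each line, the smallest that 1000 shuffles can give). The shuffles treat regions as independent, which neighbouring regions are not. They show only that regions of a class cluster, not why. The splitting of single wide domains into many peaks is argued against as the whole cause, since after joining peaks across 5 kb the longest runs held 19 and 18 regions, against at most 9 and 13 in shuffles (permutation p = 0.000999), although runs of 8 or more regions fell from 31 to 14 in OCI-Ly1 and from 216 to 44 in OCI-Ly7. In 8 of the 10 longest runs, 5 per line, at least 1 peak of the other line lay within the span. Whether DNA loss in the other line or a regional difference in chromatin lies behind the runs was not tested.

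The commonest peak width was 169 bp in all 4 lists, the width of 432, 554, 495 and 559 peaks in OCI-Ly1 replicate 1, OCI-Ly1 replicate 2, OCI-Ly7 replicate 1 and OCI-Ly7 replicate 2. Regions found in a single library had low peaks, with median heights of 28, 35, 32 and 31 in that order, against median heights of 56, 65, 67 and 65 over all peaks of each list.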
